A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

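RNA from Saccharomyces cerevisiae was compared on 5 spotted 2-channel arrays. Each array carried cDNA from RNA co-purified with zzYra1 by immunoprecipitation (IP) in one channel and cDNA from total RNA in the other. Per the labels, the IP RNA was in channel 1 on arrays 1 and 3 and in channel 2 on arrays 2, 4 and 5. The deposited tables cover 2 array platforms. Arrays 1 and 2 have 7680 spots each, and arrays 3, 4 and 5 have 12800 spots each.

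The deposited values are log10 ratios of the 2 channels per spot. Neither the base of the logarithm, the direction of the ratio nor any processing step is given in the sources used here. The base was settled from the values. For each value, the simplest fraction whose log10 rounds to the printed decimals was found. It had both terms at most 65535 and a product under 100000000 for between 36.8% (array 3) and 93.9% (array 4) of the values, against 6.7% to 7.95% of 2000 values per array jittered by up to 0.01. With base 10, 17.3% of the linear ratios of array 5, each taken with the larger channel on top and multiplied by 100, were whole within 0.001, against 0.134% for base 2 and 0.215% for base e. On arrays 1 to 4 the share with base 10 was only 1.87%, 1.16%, 0.553% and 0.407%. Why array 5 stood apart was not tested. Many of its ratios, which form replicate 4, may differ in kind from those of the other arrays. The fractions give the channel intensities up to a common factor. These are used to describe spot brightness, to remove a trend of ratio on brightness in checks of the results, and to compare the channels of gene lists. They did not enter the tests of genes and lists. Medians of the deposited log10 ratios lie far from 0 on most arrays, so the channels had not been balanced. The direction stays unknown, and scale and centring are set here.

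Values were multiplied to the log2 scale, and each array was centred on its own median. A ratio is therefore relative to the median spot of its array. Spots with no value were left out. Spots were named through GEO's platform annotation, which is old. Of the spots, 6695 on the first platform and 11138 on the second carried 1 gene, none carried several, and 985 and 1662 were unnamed here. Symbols were updated through gene identifiers in RefSeq assembly R64, which held 5578 of the 5583 genes of the first platform and 5534 of the 5539 of the second. Spots of 1 gene were averaged. The assembly was used for names and gene lengths only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for this and for the plots.

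Arrays 1 and 2 share a label set with the channels exchanged. They may be a dye swap of the same extracts, so their mean counted as 1 replicate (replicate 1), and arrays 3, 4 and 5 were replicates 2, 3 and 4. Where only 1 of the pair had a value, it stood for replicate 1. Of the tested genes, 475 had both, 225 had array 1 alone and 3 had array 2 alone, so the channel holding the IP RNA in replicate 1 differs between genes. The labels do not say whether these came from separate cultures, so p-values measure only the spread between these arrays. Each ratio is formed and centred within 1 array, which is why arrays of both tables entered the same fit. The 703 genes measured in all 4 replicates were tested against 0 with limma's lmFit and eBayes (limma 3.58.1, R 4.3.3, statmod 1.5.0), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 11 lists that had at least 5 tested members. The lists were cytosolic and mitochondrial ribosomal proteins, translation factors, ribosome biogenesis, glycolysis and fermentation, oxidative phosphorylation, cell wall, plasma membrane transporters, chaperones, amino acid biosynthesis, proteasome, histones, mRNA export factors, ergosterol and fatty acid synthesis, cell cycle, vacuole, secretory pathway, intron-containing genes, mitochondrially encoded genes, non-coding RNA genes and Ty element genes. Within single arrays a list's mean was placed among 10000 random lists of the same size, drawn as independent genes and not matched on expression level. Genes above the 80th or below the 20th percentile in every replicate were counted against 10000 permutations of ranks within replicates (setting 20 percent, with 10 percent as the alternative).

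The design fixed that arrays would be turned if those of opposite channel assignment correlated below 0, kept as deposited if all correlated above 0, and reported with no direction otherwise. The third case applied. Values are kept as deposited, "higher" and "lower" refer to the deposited ratio, and fits with the channel 2 arrays turned are given as an alternative. Genes named are the 12 of each sign with the smallest p, since none passed the threshold, YRA1, and the highest and lowest tested member of each list. Other alternatives changed the replicate unit, centring, scaling, platform, missing values, spot averaging, variance model, threshold and replicates. Alternatives chosen after seeing the data turned the channel 2 arrays, removed a running median over 81 neighbouring spots, left out array 1, used the channel 2 arrays alone, combined the turned or the channel 2 arrays with an estimated correlation, or tested lists on genes measured in at least 3 replicates.

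The test was tried on simulated values for these 703 genes with the measured spreads and 200 changed genes in 50 runs. It recovered 0.88% of genes shifted by 0.5, 2.8% of those shifted by 1, 38.7% of those shifted by 2 and 69.1% of those shifted by 3 on the log2 scale. Of the genes called, 4.66% were false. These rates hold for 200 changed genes among 703, and recovery would be lower with fewer changed genes, since the adjustment is then stricter. A list of 40 genes shifted by 0.5, with genes simulated as independent, had an unadjusted camera p under 0.05 in 100% of 50 runs at the preset correlation and in 88% with an estimated one. An unshifted list did in 2% and 0%. These runs do not give the power at an adjusted p or for correlated genes. The number of arrays limits the precision, and for the median gene the 95% interval reached 1.40 to either side of the mean on the log2 scale. No intensity columns were analysed here, so no filter on dim spots was applied. Many deposited values were already missing, however. A value was present for 98.8%, 64.2%, 38.2%, 48.0% and 29.1% of spots on arrays 1 to 5, and the reason is not given. The tested genes are thus a selected set, 703 of the 5583 genes of the first platform. They include 51 of 135 ribosomal protein genes and 13 of 30 glycolysis genes, so these lists are over-represented among them.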

Results

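RNA bound to Yra1, an RNA-binding adaptor of nuclear mRNA export in budding yeast, was compared with total RNA on 5 arrays. The zz prefix of the tagged protein is as the labels give it. The question was which transcripts were over- or under-represented in the IP relative to total RNA. Array 1 had a value for 7591 spots and 5541 genes, array 2 for 4931 spots and 3845 genes, array 3 for 4884 spots and 2705 genes, array 4 for 6143 spots and 3196 genes, and array 5 for 3722 spots and 1717 genes. No mock precipitation was among the samples analysed here.

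The 2 channels differed widely in overall level. The median deposited log10 ratio was -1.39 on array 1, 1.34 on array 2, -0.853 on array 3, 0.302 on array 4 and -0.141 on array 5. The arrays with IP RNA in channel 1 thus had medians below 0, and of those with IP RNA in channel 2, arrays 2 and 4 lay above 0 and array 5 below. On the log2 scale the spread of single spots (SD) ran from 0.848 on array 2 to 2.30 on array 5.

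**Figure D1:**
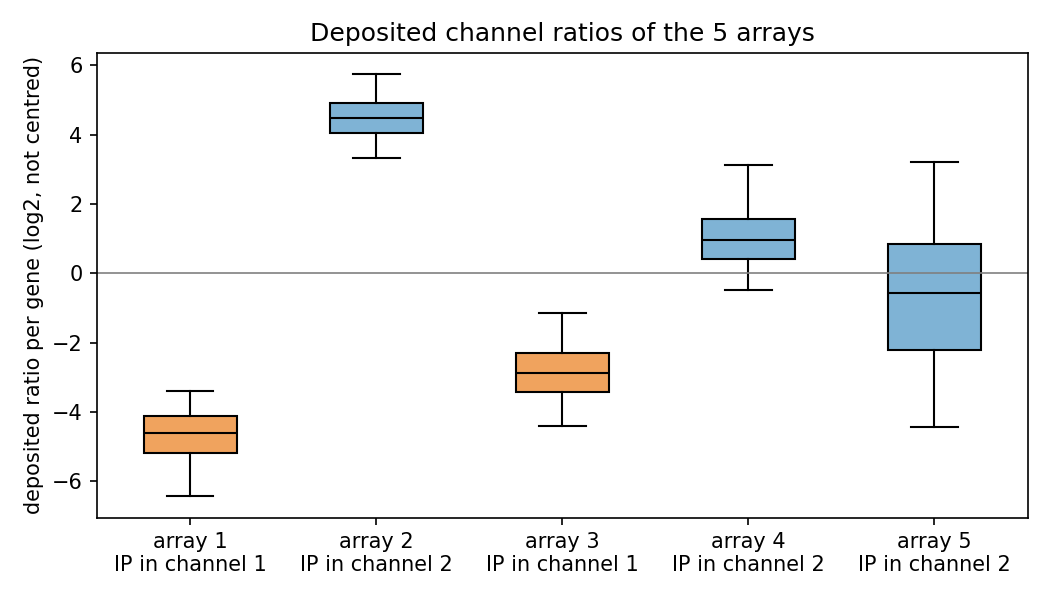
Deposited ratio per gene on the log2 scale before centring, for each of the 5 arrays, coloured by the channel that held the IP RNA. Boxes show the quartiles and median and whiskers the 5th and 95th percentiles. The spot medians are -4.60, 4.47, -2.83, 1.00 and -0.47 for arrays 1 to 5.

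Arrays shared little of their ratios. Across genes, which are not independent replicates, the 10 pairs of arrays had a median Pearson correlation of 0.048, and 2 pairs fell below 0. The highest value was 0.23 (95% interval 0.171 to 0.287), between arrays 3 and 5 over 1025 genes, and the lowest was -0.045, between arrays 1 and 3 over 2680 genes. The possible dye swap, arrays 1 and 2, gave 0.0077 over 3814 genes. Pairs with the same channel assignment averaged 0.068 and pairs with opposite assignment 0.060. The correlations did not settle whether the deposited ratios follow the channels or all run from IP to total RNA or from total RNA to IP. In what follows, higher and lower describe the deposited ratio as it stands. The medians changed sign with the channel of the IP RNA in 4 of 5 arrays, and those of arrays 1 and 2 nearly mirrored each other. The titles name IP before total RNA, but the direction of the ratio is not given in the sources used here.

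The 12 genes with a positive mean ratio and the smallest p included 4 ribosomal protein genes and 1 glycolysis gene. RPL21A, a ribosomal protein gene of the large subunit, had a mean log2 ratio of 2.89 ± 1.58 (SD, n = 4), DBP2, an RNA helicase, 2.87 ± 1.74, SSA2, a cytosolic Hsp70 chaperone, 2.47 ± 1.31, and ADH1, the main fermentative alcohol dehydrogenase, 2.38 ± 1.92. The ribosomal protein genes RPL21B, RPL7B and RPS21B had means of 2.43, 2.30 and 2.10. MOR1 (2.45), HOS1 (2.02), VAC7 (1.86), PDR12, a weak-acid exporter (1.77), and ECM38 (2.11) completed the 12 genes of this sign, and all but ECM38 had a value above 0 in 4 of 4 replicates. Replicate 1 is a mean of arrays 1 and 2, however, and 5 of the 12 genes lay below the median of 1 of these arrays: ADH1 (-3.23 on array 1 and 3.86 on array 2), RPL21B (-0.40 on array 1), DBP2 (-0.26 on array 2), RPS21B (-0.09 on array 2) and ECM38 (-1.07 on array 2). Among the 12 genes of the other sign, LAP3, an aminopeptidase, had -1.88 ± 0.90 and SKP2, an F-box protein gene, -1.64 ± 0.17, the latter with nearly the same value in each replicate. YPR071W (-2.14), SUE1 (-1.98), NPR1, a protein kinase acting on nutrient transporters (-1.96), ABZ1 (-1.89), YEL067C (-1.87), PHO90, a phosphate transporter (-1.81), RAX1 (-1.79), ZWF1, the first enzyme of the pentose phosphate pathway (-1.51), SEC62 (-1.33) and REC8 (-1.20) followed. Of these 12 genes, 8 had a value below 0 in 4 of 4 replicates, and 6 lay above the median of at least 1 array. Some means leaned on 1 replicate: PHO90 and RAX1 on replicate 4 (-3.98 and -4.03), and ZWF1 and SUE1 on replicate 3 (-3.79 and -4.62). In 5 of the 12 (LAP3, SKP2, NPR1, ABZ1 and RAX1) replicate 1 was array 1 alone, and in SUE1 array 2 alone. The signs and the choice of these genes rest on the ratios as deposited. With the channel 2 arrays turned, all 12 of the first group lay below 0 (RPL21B at -2.10, SSA2 at -1.98, RPL21A at -1.26, ADH1 at -1.04) and 11 of the 12 others above 0 (SUE1 at 2.31, PHO90 at 1.74, NPR1 at 1.25), SKP2 being the exception at -0.07.

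None of these values passed the test. With limma and Benjamini-Hochberg adjustment, 0 of 703 genes had an adjusted p under 0.05 and the smallest adjusted p was 0.54, while 55 genes had an unadjusted p under 0.05 where 35.15 are expected by chance. With the channel 2 arrays turned it was 17 genes, fewer than by chance. The variant of limma's eBayes with trend and robust also called 0 genes, with 19 at an unadjusted p under 0.05. The sign was shared by all 4 replicates in 106 genes, or 15.1%, where chance gives 12.5%, and with the channel 2 arrays turned in 63 genes, or 8.96%. Genes at an unadjusted p under 0.05 numbered 26 without replicate 3 and 31 without replicate 4. The second platform alone gave 0 of 704 genes, with 65 at an unadjusted p under 0.05. In RPL7B and ECM38, replicate 1 stood apart from the other replicates.

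Ribosomal protein genes were higher as a group in the deposited ratio, but passed only at a preset correlation. With the channel 2 arrays turned they were lower (mean -0.53). The 51 tested members had a mean log2 ratio of 0.87 ± 0.64 (SD over 4 replicates), 45 of them lay above 0, and their replicate medians were 0.20, 0.78, 1.30 and 1.62. Names of 45 members end in A or B, as those of duplicated genes do, and hybridisation between such copies was not excluded. No member passed the test over all genes or adjusted over the list alone. RPL21A was the highest member and RPS22A the lowest (-1.27 ± 1.77). The group passed camera with a preset correlation (adjusted p = 1.0e-06 over 11 lists), but not with an estimated one (adjusted p = 0.60 with an estimated correlation). Genes of glycolysis and fermentation were also higher as a group, with a mean of 1.22 ± 1.01 over 13 tested members, 12 of which lay above 0. ADH1 was the highest and GPD1, which makes glycerol 3-phosphate, the lowest (-0.21 ± 0.72). With the channel 2 arrays turned, 3 of the 13 lay above 0, with ADH1 at -1.04 and GPD1 at 0.19, and of the ribosomal protein genes 15 of 51 did, with RPL21A at -1.26 and RPS22A at 1.07. As deposited, no member of the glycolysis list passed in either count, over all genes or adjusted over the list alone.

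**Figure D2:**
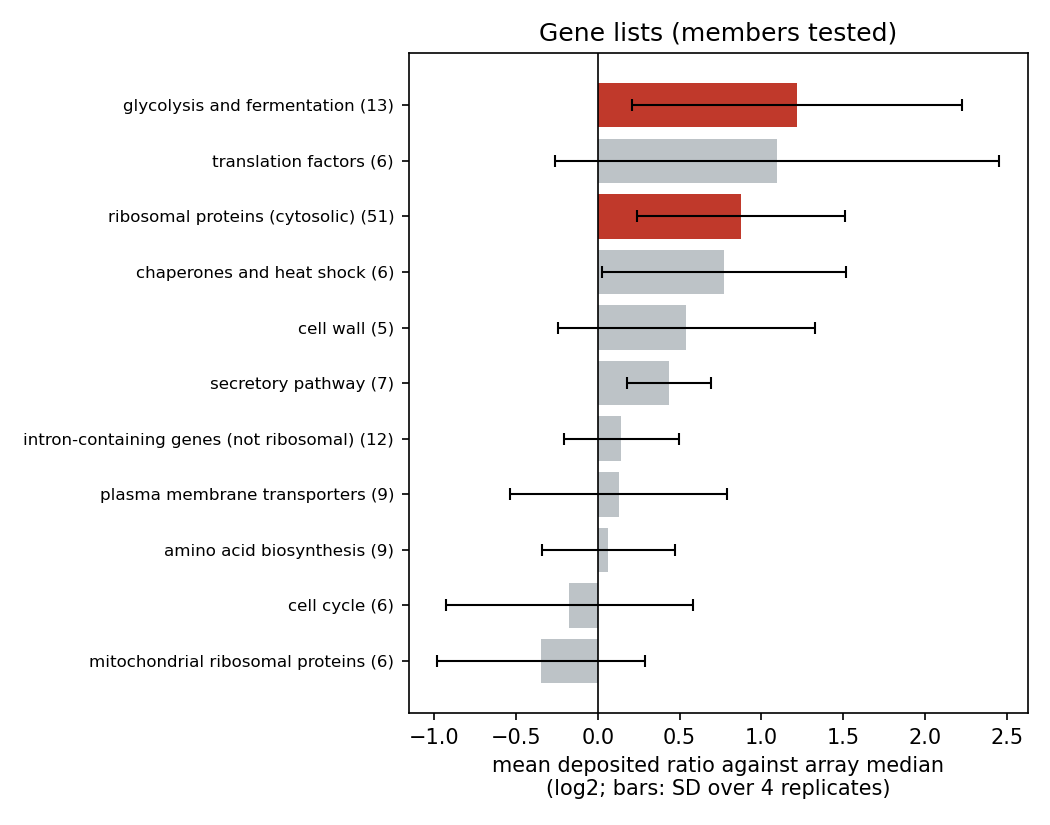
Mean deposited ratio against the array median (x axis, log2) of the 11 gene lists with at least 5 tested members, with the number of tested members in parentheses. Bars in red passed camera with a preset correlation, grey bars did not, and error bars are the SD over 4 replicates. Glycolysis (1.22) and ribosomal proteins (0.87) are the lists that passed.

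Within single arrays the group means varied, and the difference between platforms was not tested. The mean of all measured ribosomal protein genes was -0.10 ± 0.09 (SE over 135 genes) on array 1, 0.35 ± 0.13 on array 2 (97 genes), 0.68 ± 0.17 on array 3 (91 genes), 0.90 ± 0.14 on array 4 (97 genes) and 1.51 ± 0.26 on array 5 (75 genes). On arrays 2 to 5 this exceeded the central 95% of 10000 random gene lists, and on array 1 it lay at percentile 52.4. The random lists were not matched on brightness and treat genes as independent. On array 2 the median was 0.12, and with the trend of ratio on brightness removed the shift against other genes was 0.05. On array 5 that shift fell from 1.80 to 0.56 with the trend removed. It went from 1.04 to 0.97 on array 3 and from 0.58 to 0.47 on array 4. All these shifts cover recovered spots only, which can leave out the brightest. Brightness from fractions in lowest terms is inexact, so part of the trend may remain. Glycolysis genes averaged 1.09 on array 3, 1.04 on array 4 and 1.88 on array 5, all above the random lists, against 0.23 on array 2 and -0.44 on array 1, where they were below the central 95%. The brightness trend was not removed for this list. Among recovered spots, both terms of its ratio were brighter than for all genes, by 2.43 and 1.00 (array 3), 1.44 and 0.48 (array 4) and 3.82 and 1.48 (array 5). A brightness trend therefore stays open for glycolysis genes. Because arrays 3 and 4 had opposite channel assignments and both showed higher values, the direction of the pooled mean depends on how the ratios run. Turning the channel 2 arrays gave -0.53 for ribosomal proteins (camera, adjusted p = 0.0012 at the preset correlation and 0.63 with an estimated one) and -0.65 for glycolysis (camera, adjusted p = 0.044 and 0.63). In the 3 arrays with IP RNA in channel 2, which run the same way in either case, the means were 1.00 (camera, adjusted p = 7.5e-06 at the preset correlation and 0.56 with an estimated one) and 1.48 (camera, adjusted p = 0.00040 and 0.56), with the direction relative to total RNA still unknown.

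**Figure D3:**
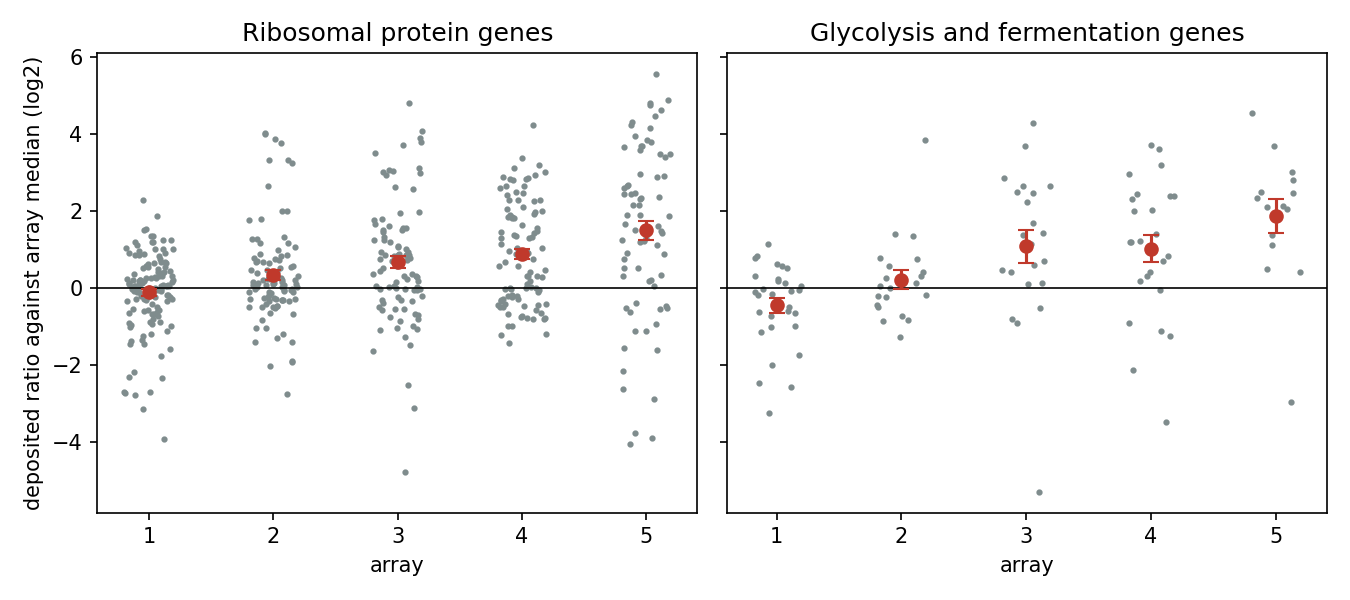
Deposited ratio against the array median (y axis, log2) of each measured ribosomal protein gene (left) and glycolysis or fermentation gene (right) on arrays 1 to 5. Grey points are genes and red points the list mean with its SE over genes. Ribosomal protein means run from -0.10 on array 1 to 1.51 on array 5.

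The other 9 tested lists did not pass. Translation factors had a mean of 1.10 ± 1.36 over 6 members (adjusted p = 0.068), with TEF2, an elongation factor gene, at 2.67 ± 2.68 and EFT1 at 0.21 ± 0.87. Chaperones had 0.77 ± 0.74 over 6 members, from SSA2 down to SSE1 (-0.48), and SSA2 alone passed when adjusted over the list alone. Cell wall genes had 0.54 ± 0.79 over 5 members, led by the mannoprotein gene CCW12 (1.98 ± 1.62), with GSC2 lowest (-0.57). Secretory pathway genes had 0.44 ± 0.26 over 7 members, from YDR292C, which encodes a subunit of the signal recognition particle receptor (1.57), to SEC62. Plasma membrane transporters had 0.13 ± 0.66 over 9 members, from HXT6 (1.43) to PMA2 (-1.0), and amino acid biosynthesis genes 0.062 ± 0.41 over 9 members, from HOM2 (1.55) to LYS12 (-0.76). Cell cycle genes had -0.17 ± 0.75 over 6 members, from SWI4 (0.50) to CLN1 (-0.89), and mitochondrial ribosomal proteins -0.35 ± 0.64 over 6 members, from MRP1 (0.42) to MRPS12 (-1.27). The 12 tested intron-containing genes outside the ribosomal proteins averaged 0.14 ± 0.35, with a median of -0.057, from DBP2 to TFC3 (-1.18), and DBP2 alone passed when adjusted over the list alone. For transporters and amino acid biosynthesis, camera's direction was lower while the mean was positive, and for amino acid genes the median was -0.33. Without replicate 4, the means were 0.51 for translation factors, 0.19 for cell wall genes (camera's direction lower), -0.10 for mitochondrial ribosomal proteins, -0.20 for transporters, 0.18 for cell cycle genes, 0.26 for amino acid biosynthesis and 0.31 for intron-containing genes, none past the threshold. Without replicate 3 the mean was 0.45 for chaperones, -0.020 for amino acid biosynthesis and 0.028 for intron-containing genes. Without replicate 2 it was -0.011 for amino acid biosynthesis and -0.59 for mitochondrial ribosomal proteins, and without replicate 1 it was -0.40 for cell cycle genes. With the channel 2 arrays turned, the means were -0.71 for chaperones, -0.60 for cell wall genes, -0.42 for translation factors, -0.37 for transporters, -0.20 for secretory pathway genes and -0.0062 for intron-containing genes. They were 0.55 for mitochondrial ribosomal proteins, 0.27 for cell cycle genes and 0.17 for amino acid biosynthesis, again none past the threshold. Several of the named extremes rest on replicate 4. Without it the value was -0.045 for MRPS12, -0.40 for RPS22A, -0.43 for PMA2, -0.18 for EFT1, -0.0081 for HXT6, 0.33 for LYS12, 0.22 for GSC2, 0.040 for SSE1 and 0.042 for TFC3. The extremes also depend on the direction: turned, the highest member of each list fell below the lowest (HXT6 at -1.33 and PMA2 at 0.33) in every tested list except cell cycle genes. With arrays scaled to the same spread, the mean turned to -0.062 for transporters and 0.062 for cell cycle genes. Among genes measured in at least 3 replicates, the means were 0.41 for translation factors (24 members) and 0.042 for chaperones (15 members). They were 0.11 for secretory pathway genes (18 members), -0.086 for intron-containing genes (37 members) and 0.24 for amino acid biosynthesis (36 members). None of these was past the threshold. A single replicate stood apart in YDR292C, HXT6, MRP1 and TFC3.

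YRA1 itself had values on only 2 arrays, 0.12 on array 1 and -0.014 on array 3, and was not tested, since the fit took only genes measured in all 4 replicates. Among the other mRNA export factors, GLE2 had 0.44 ± 0.58, GFD1 -0.51 ± 0.58 and MTR2, the partner of the export receptor Mex67, -1.0 ± 1.84, none past the threshold (adjusted p of 0.76, 0.73 and 0.67 with limma). The value of MTR2 rested on replicate 4 (-3.67), without which the mean was -0.11. Without replicate 4, GLE2 had 0.22 and GFD1 -0.24, and without replicate 3, GLE2 had 0.69. With the channel 2 arrays turned, MTR2 had 0.77, GFD1 0.33 and GLE2 -0.08. GFD1 lies outside the naming rule and was chosen after its values were seen, to complete the 3 tested members.

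By rank, MOR1, RPL21A, DBP2, VAC7 and PDR12 were in the top 20% of the 703 genes in all 4 replicates. These 5 genes compare with a mean of 1.15 in 10000 permutations of ranks (one-sided permutation p = 0.0062, adjusted over both ends 0.0124). In the bottom 20%, LAP3 was the single gene, against 1.11 in the permutations (one-sided permutation p = 0.68). With the channel 2 arrays turned the top count was 1, against 1.13 in the permutations (permutation p = 0.68). Without replicate 4 it was 7 (permutation p = 0.34). With each of the 5 arrays as a replicate it was 1, against 0.15 in the permutations (permutation p = 0.14). It was 29 without replicate 1 (permutation p = 1.0e-04), 14 without replicate 2 (permutation p = 0.0010) and 11 without replicate 3 (permutation p = 0.020). With the position trend removed it was 9 (permutation p = 1.0e-04), and without array 1 it was 5 of 478 genes (permutation p = 8.0e-04). The top 10% held 2 genes, against 0.074 in the permutations (permutation p = 0.0025), and the bottom 10% held 0. Without replicate 2 the bottom count was 12 (permutation p = 0.0075). Gene length, from the R64 annotation and including introns, was nearly unrelated to the mean ratio across genes (Spearman's rho 0.032 over 703 genes), and per array rho ran from -0.027 on array 3 to 0.046 on array 5.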

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

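The tests of slide position, of spot names on arrays 1 and 2, of the ribosomal protein percentile as a check on names, and of the direction were chosen only after the result, or a closely related one, had been seen. Of 61 named genes and list medians, 8 had 1 replicate standing apart from the other 3 by Dixon's test at 95%. The nominal rate of 1 in 20 would give 3.05, for replicates of equal spread and genes not picked by their means. Many of these genes were picked as the extreme member of a list and the arrays differ in spread. The 8 are therefore not read as an excess. Replicate 1 stood apart in RPL7B (0.40) and ECM38 (-0.39). Replicate 3 stood apart in COX9 (-5.83) and YDR292C (3.16). Replicate 4, the array with the widest spread, stood apart in MRP1 (1.21), HXT6 (5.76), PRE3 (-3.42) and TFC3 (-4.85).

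The arrays shared little of their ratios across genes. Uneven signal over the slide, as far as a running median over 81 spots removes it, is argued against as the whole cause. The median correlation of the 10 pairs was then 0.045. Weak signal in dim spots could be examined only among recovered spots, 36.8% of the values on array 3. The brightest spots could drop out there. Brighter genes raised the median correlation by 0.037. Single pairs moved from 0.11 to 0.22 (arrays 2 and 4) and from -0.026 to -0.058 (arrays 1 and 3). Brightness here was the mean of both channels on the log2 scale, from fractions in lowest terms. A gene could thus count as bright with 1 dim channel. The median terms were 164 and 4051 on array 1 and 5201 and 239 on array 2. Weak signal in 1 channel therefore stays open. Names scattered at random over the spots are argued against on array 2. Spots of 1 gene over 50 positions apart correlated there at 0.31 (95% interval 0.221 to 0.392). This only shows that spots sharing a name agree. Names exchanged between whole genes would pass it, so wrong gene names stay open on array 2. Wholly unrelated names are argued against on arrays 3 to 5, where ribosomal protein genes lay at percentile 100 among random lists of the same size. On array 1 the correlation of far-apart spots was 0.092 (0.033 to 0.150), above 0 but not clear of the bound of 0.1. On the second platform only array 4 gave such a value (0.36, -0.240 to 0.759, over 13 pairs). Mismatched names therefore stay open on array 1 and the second platform. Differences between the precipitations themselves also stay open and were not tested.

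The deposited ratios of ribosomal protein genes were higher on arrays 3, 4 and 5 than those of other genes. A trend of ratio on spot brightness is argued against as the whole cause for recovered spots only, which can leave out the brightest. Even there it holds only as far as fractions in lowest terms measure brightness. The common factor of each spot is lost, so part of the trend may remain. They covered 55 of 91 measured members on array 3, 88 of 97 on array 4 and 64 of 75 on array 5. With the trend removed, their median shift went from 1.04 to 0.97 on array 3 and from 0.58 to 0.47 on array 4. On array 5 it went from 1.80 to 0.56, so most of the shift there went with brightness. The rank-test p with the trend removed ran from 2.6e-07 to 0.00093 over genes, which are not replicates. Over all 91 members on array 3 the median ratio was 0.59. For members not recovered, a brightness trend stays open. On array 2 the shift was 0.09 before and 0.05 after, so nothing beyond brightness is claimed there. A position trend is also argued against as the whole cause, since the pooled median was 0.75 with it removed. Of the 16 ways to turn the arrays, 1, the deposited one, gave a list p as small (9.4e-08, next 1.3e-07), and 16 are too few for a share under 0.05. A dye effect on abundant transcripts, hybridisation between duplicated genes and an association with Yra1 unlike that of the median gene stay open.

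The direction of the deposited ratios could not be settled. With position and brightness trends removed, pairs of opposite channel assignment had a mean correlation of 0.063, and arrays 3 and 5 one of 0.247 (0.154 to 0.335), where ratios that follow the channels and differ only by a shared IP effect would fall below 0. That reading was not excluded, because a dye preference fixed to each gene raises pairs of both kinds when ratios follow the channels, and same-assignment pairs averaged a similar 0.074. Ratios already turned to 1 direction with little shared dye effect, and ratios that follow the channels with a shared dye effect and little shared IP effect, therefore cannot be told apart. The array medians changed sign with the channel of the IP RNA in 4 of 5 arrays (-1.39 and 1.34 on arrays 1 and 2), which ratios that follow the channels would give where the RNA amounts differ, and turned ratios would give where the dyes differ in signal, so they leave both readings open. These reasons for leaving the direction open were added after the values were seen.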

How the results depend on the processing

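Turning the channel 2 arrays (with either correlation), removing the position trend, leaving out array 1, using channel 2 arrays alone (with either correlation) and testing lists on genes measured in at least 3 replicates were chosen after seeing the data. No paired analysis was possible because all arrays form 1 group. The count of genes past the threshold was 0 under the main setting and all 19 alternatives run, with between 475 and 2422 genes tested and 11 to 119 genes at an unadjusted p under 0.05. All 16 sign patterns of the arrays gave 0 genes (real 0, highest other 0), and 16 are too few for a share under 0.05. A random block for the label set gave no estimate, because 4 blocks among 5 arrays are too few for the tool, and the first platform alone holds 1 replicate, so neither was run. Of the gene lists, 2 passed; with an estimated correlation 0 did, with means unchanged at 0.87 for ribosomal proteins and 1.22 for glycolysis. Without 1 replicate, 2 to 3 lists passed, and the means ran from 0.65 to 1.15 and from 0.88 to 1.68. Turning the channel 2 arrays reversed both, to -0.53 and -0.65, and gave 1 gene in the top 20%, where permutations average 1.13 (permutation p = 0.68). Counting each array as a replicate gave 1 gene of 475, where permutations average 0.15 (permutation p = 0.14), and left the means at 0.79 and 1.16. With the channel 2 arrays turned and an estimated correlation, no list passed camera (adjusted p = 0.63 for both). None did on the channel 2 arrays alone with an estimated correlation (0.56 for both, means 1.00 and 1.48). Leaving out 1 replicate gave 7 to 29 genes in the top 20%, where permutations average 5.65 to 5.71, and 2 to 12 in the bottom 20%, where they average 5.56 to 5.58. The length correlation ran from -0.0058 to 0.046 without 1 replicate and was -0.072 with the channel 2 arrays turned. Cell wall genes passed (mean 0.51, adjusted p = 0.034) at the preset correlation among genes measured in at least 3 replicates, where no correlation was estimated. On the 703 genes their adjusted p was 0.50, or 0.60 with an estimated correlation. Translation factors passed without replicate 1 (adjusted p = 0.046) or 3 (0.023), but not without replicate 2 (0.15) or 4 (0.49), nor with an estimated correlation (0.60). None of 885 values of named genes under alternatives passed (smallest adjusted p 0.13), and 78 had the other sign, 46 of them with the channel 2 arrays turned, 8 without centring and 24 elsewhere. The cause was not tested.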

Other observations

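The 18 lists with measured members, the 11 of the pooled test included, were compared within single arrays. Of the 90 values, 16 lay above and 4 below the central 95% of random lists. Ribosomal proteins gave 4 of those above, and glycolysis 3 above and 1 below. Of the lists too small for the pooled test, only histones (1 above) and mRNA export factors (1 below) lay outside. The 4.5 expected by chance treats genes as independent. Neighbouring spots of different genes correlated at 0.17 (array 2) to 0.74 (array 5), so chance may give more. With the channel 2 arrays turned, the counts would be 7 above and 13 below, so above and below refer to the deposited ratio. The random lists were not matched on brightness, and on array 5 the ratio rose with brightness (Spearman's rho 0.60 across spots), where the upper term of the ratio was shifted by 1.83 for histones and -2.01 for mitochondrial ribosomal proteins. On array 5, histone genes averaged 2.02 ± 0.47 (SE over 5 genes) and lay above random lists, as did translation factors (1.65 ± 0.50) and plasma membrane transporters (1.41 ± 0.80), while mRNA export factors averaged -1.66 ± 0.70 over 10 genes and mitochondrial ribosomal protein genes -1.14 ± 0.40 over 22 genes, both below. On array 1, mitochondrial ribosomal protein genes (0.17 ± 0.10), amino acid biosynthesis genes (0.17 ± 0.10) and cell cycle genes (0.17 ± 0.15) lay above random lists and chaperones (-0.42 ± 0.20) below. On arrays 1 to 4 histones and export factors lay inside the central 95%. Cell wall genes lay above random lists on array 2 (0.43 ± 0.20) and array 5 (1.47 ± 0.61). Intron-containing genes outside the ribosomal proteins did so on array 2 alone (0.28 ± 0.09). Ribosome biogenesis, oxidative phosphorylation, proteasome, ergosterol and fatty acid synthesis, vacuole and secretory pathway genes lay outside on no array. Tested members of the small lists ran from DBP2 to DBP3 (0.065) for ribosome biogenesis, from ATP7 (0.67) to COX9 (-1.04) for oxidative phosphorylation, from RPN13 (0.046) to PRE3 (-0.97) for the proteasome, with 1 replicate standing apart in COX9 and in PRE3, and from ELO2 (0.34) to MVD1 (-0.21) for lipid synthesis. The order reversed, with the channel 2 arrays turned, for oxidative phosphorylation (ATP7 at -0.43, COX9 at 1.84) and the proteasome (RPN13 at -1.09, PRE3 at 0.70), while DBP2 (-0.15) stayed above DBP3 (-0.34) and ELO2 (-0.04) above MVD1 (-0.36). COX9 was at 0.55 without replicate 3. Without replicate 4, PRE3 was at -0.16, RPN13 at -0.72, DBP3 at -0.41 and MVD1 at 0.11. ATP7 and ELO2 were also highest in replicate 4 (2.22 and 0.83), against at most 1.29 and 0.36 in the other replicates. Mitochondrially encoded, non-coding RNA and Ty element genes were not analysed here.

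The intensities recovered from the fractions give a view of each channel. The term above the line of the ratio was brighter for ribosomal protein genes than for all genes by 1.55, 0.85 and 2.17 on the log2 scale on arrays 3, 4 and 5, and the term below the line by -0.25, 0.096 and 0.25. On arrays 1 and 2 both terms differed by at most 0.13. For glycolysis genes the upper term was brighter by 2.43, 1.44 and 3.82 and the lower term by 1.00, 0.48 and 1.48 on arrays 3 to 5. Fractions are reduced to lowest terms and were recovered for 36.8% of the values on array 3, so these shifts describe the spots that could be recovered.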
